A study of Danio rerio with 8 samples.

How the data were processed

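Total RNA of whole zebrafish (AB line) was measured in 4 gfp and 4 usp39 samples, 1 file of counts per sample. Per the labels' protocols, tissue was homogenised in RNAzol RT, 1.0 µg of RNA per sample went through removal of rRNA with a kit made for human, mouse and rat, and CORALL libraries were sequenced. Per the submitters' processing notes, Trimmomatic 0.40, STAR 2.7.11a, HTSeq 1.99.2 and DESeq2 1.42.1 were used with the genome build GRCz11, and the notes do not say for which step each served. The deposited values are raw counts of reads per Ensembl gene, whole numbers with no normalization, for 32520 genes. Each file also holds 5 summary counts of the counting tool, whose names start with __, for reads in no gene, in more than 1 gene or aligned more than once. These stayed out of library sizes and tests and were used as shares only. Reads in no gene made up 40.1 to 49.5% of uniquely placed reads, and the 95% exact binomial interval of each share is narrower than 0.1 percentage points. The strand setting of the counting, the annotation release and the handling of molecular identifiers are not given in the sources used here, so overlapping and antisense genes are uncertain, as are genes with near-identical copies.

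Gene symbols came from a table that pairs Ensembl IDs with symbols, which matched 29201 of the 32520 IDs (23163 of those tested). 1806 symbols stand for more than 1 ID, and such genes are given with their ID. A RefSeq table of assembly GRCz12tu was used only for names, for which genes are protein-coding (19690 of those tested) and for the order of genes along a chromosome. No coordinates are given.

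Counts were tested with R 4.3.3 and edgeR 4.0.16. Genes with low counts were removed by filterByExpr with the group as factor, which left 24986, and library sizes were scaled by TMM factors. The quasi-likelihood F test with robust dispersion compared the 4 usp39 with the 4 gfp libraries, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. CPM were computed by edgeR on TMM-scaled library sizes. The common dispersion was 0.00929, a biological coefficient of variation of 9.64%. Replicates differed by more than counting noise, with chi-squared per degree of freedom of 3.34 to 22.4 between pairs of a group. The p-values measure spread between samples, and the labels do not say whether samples came from separate clutches or animals. Intervals for shares cover counting error only.

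Lists of genes for pathways and cell types were written before the data were examined, 47 in all with 2297 symbols, of which 2166 matched a gene in the files, 1724 exactly, 412 without a paralog suffix and 30 by a synonym. The test, the named-gene rule and the main alternatives were fixed at the same time. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list. Fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes, was an alternative. An exact permutation test also set each list's median log2 fold change against the other splits of the 8 libraries into 4 and 4, two-sided, 35 splits in all. Library measures were compared by exact permutation of the 70 assignments, two-sided.

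Named genes are usp39, the 12 genes per direction with the largest log2 fold change and, from each list, up to 4 members with the lowest p. The 12 had to have an adjusted p under 0.05, a mean CPM of at least 5, no overlap between the groups, a protein-coding annotation and a symbol that is not a clone name. 10 genes that rose and 2 that fell met the other criteria but were passed over for their name or biotype before the 12 were reached. Where 5 or fewer members of a list moved 1 way, most are named too, chosen after their values were seen, as are the genes of the closing section except the foxj1 genes. Not every gene that the rule takes is named.

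The test was checked on simulated counts with real means and library sizes of the 24986 tested genes. Of 200 genes changed, 50 per fold, it recovered 10% at 1.25-fold, 72.0% at 1.5-fold, 92.0% at 2-fold and 100% at 4-fold. Of 147 calls, 10 were false. With the proteasome list shifted 1.25-fold, its adjusted p was 2.22e-97 and 2.98e-05 (camera, preset and estimated correlation) and 1.91e-05 (fry). Of 46 other lists, 0 were called. Simulated genes were uncorrelated, so tests of correlated lists stay unchecked.

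Alternatives were RLE, upper-quartile and library-size scaling, no low-count filter, a filter of CPM of at least 1 in 4 samples, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, libraries without mitochondrial and rRNA genes, protein-coding genes only, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each library in turn. The labels do not say whether a replicate number pairs the samples. After removal of group means, the correlation across genes between a gfp and a usp39 library of the same number was 0.155, 0.122, -0.0105 and -0.0324 for numbers 1 to 4. For 2 of the 4 numbers the gfp and usp39 libraries matched each other best, so a pairing stays open. A trend with exon number and a contrast of nested genes had been planned and were left out, since they need a GRCz11 annotation that was not used here.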

Results

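RNA from whole zebrafish (Danio rerio, AB line) was sequenced in 8 libraries, 4 labelled gfp with a wild-type genotype and 4 labelled usp39. Usp39 is a protein of the spliceosome, the complex that removes introns, and joins it with the U4/U6.U5 tri-snRNP. The comparison asked which transcripts differ in whole animals when usp39 is targeted, in a series whose title names cryptic splicing, ubiquitination and ER-phagy. The sample labels name a CRISPR/Cas9 knockout for the usp39 libraries, whereas the series description names a morpholino knockdown, and no label gives an age or stage. Reads counted in genes came to 23495460, 25896197, 23962612 and 20224374 in gfp replicates 1 to 4. The usp39 replicates 1 to 4 held 25713551, 22896732, 21437269 and 26283316. Levels are given in CPM (counts of a gene scaled to library size), as mean ± SD with n = 4 libraries per group, and log2 fold changes of usp39 over gfp with ± SE where a second value follows. A signed number alone in parentheses after a gene is its log2 fold change. Counts of genes that rose or fell rest on edgeR alone. For a named one, the 4 usp39 values lay wholly above or below the 4 gfp values unless an overlap is stated.

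The usp39 transcript was not lower in the libraries labelled usp39. It stood at 15.4, 17.3, 15.6 and 17.5 CPM in gfp replicates 1 to 4 and at 16.7, 18.8, 17.0 and 18.4 CPM in usp39 replicates 1 to 4. Each value of usp39 (ENSDARG00000041908) rested on 352 to 481 counts. The log2 fold change was 0.11 ± 0.08, with a 95% interval of -0.07 to 0.29 and an edgeR adjusted p of 0.307. Counts per gene show neither an edited sequence nor a block of splicing or translation, so this value checks the labels only in part. The libraries are therefore called by their labels, and directions are given as libraries labelled usp39 against gfp.

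Transcripts of 11950 of 24986 tested genes differed between the groups, 6036 higher and 5914 lower in the libraries labelled usp39 (47.8% of tested genes, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most of the differences were small. At least 2-fold differences were seen for 1677 of these genes, 825 higher and 852 lower. The 4 usp39 values lay wholly to 1 side of the 4 gfp values for 10740 genes (43.0%), where chance gives 2.86%. Each of the 8 libraries was closest to a library of its own group, with r across genes of 0.983 to 0.992 within groups and 0.952 to 0.969 between them. Genes are not independent replicates in these correlations. Of 47 lists of genes for pathways and cell types, camera called 30, 17 up and 13 down. With a correlation estimated per list, 2 of those calls held, acute inflammation and myeloid and lymphoid markers.

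**Figure D1:**
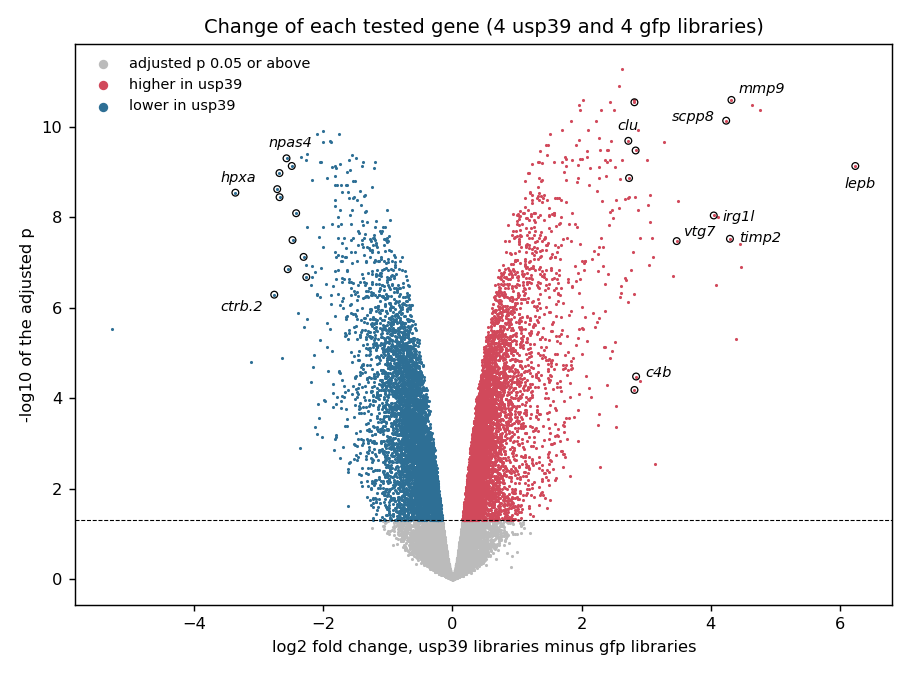
Each point is 1 of the 24986 tested genes, with its log2 fold change (usp39 minus gfp libraries) across and -log10 of its edgeR adjusted p upward, red where higher and blue where lower in usp39, grey where the test was not passed. Circles mark the 12 genes per direction with the largest change under the naming rule, from -3.36 for hpxa to 6.24 for lepb.

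Reads that entered no gene count were compared as well. Reads outside annotated genes made up 48.0 ± 1.40% of uniquely placed reads in gfp and 43.1 ± 2.48% in usp39 (SD, n = 4, exact permutation p = 0.0286, two-sided). Alignments that were not unique made up 8.16 ± 0.304% of all placed reads in gfp and 9.15 ± 0.439% in usp39 (SD, n = 4, exact permutation p = 0.0286). The number of genes with a count was 30283 ± 94.9 in gfp and 30024 ± 99.2 in usp39 (exact permutation p = 0.0286). This is the smallest p that 4 libraries against 4 allow, and after adjustment over the 10 library measures compared all 3 values stood at 0.0952. The share of counts on mitochondrially encoded protein genes was 3.82 ± 0.293% in gfp and 3.93 ± 0.324% in usp39 (exact permutation p = 0.600).

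**Figure D2:**
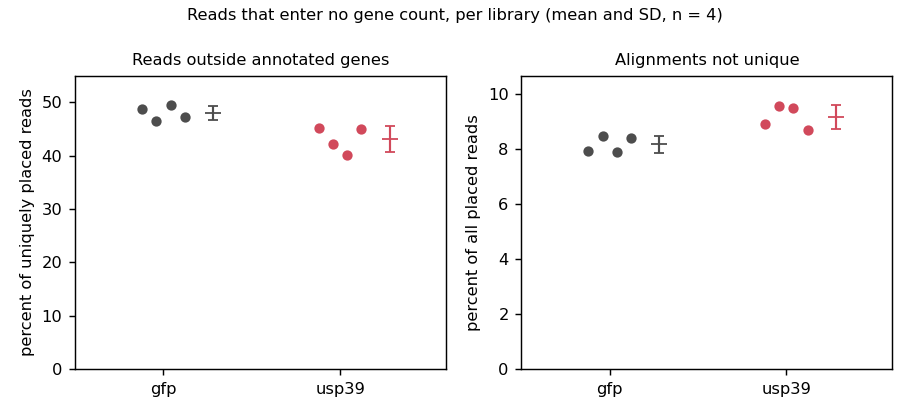
Points are single libraries and bars the mean ± SD of 4, with reads outside annotated genes as percent of uniquely placed reads (left) and alignments not unique as percent of all placed reads (right). The usp39 libraries lay at 40.1 to 45.2% on the left, below the gfp libraries at 46.5 to 49.5%.

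Among the genes that met the naming rule, the leptin gene lepb rose most and the plasma protein gene hpxa fell most, and digestive enzymes were 8 of the 12 that fell most. The hormone gene lepb (ENSDARG00000045548, 0.172 ± 0.128 to 13.2 ± 3.12 CPM, log2 fold change 6.24 ± 0.30) rose in each usp39 library. The matrix metalloproteinase mmp9 (ENSDARG00000042816, 5.56 ± 1.52 to 112 ± 7.67 CPM, log2 fold change 4.32 ± 0.14), the metalloproteinase inhibitor timp2 (ENSDARG00000075261, 13.6 ± 3.84 to 268 ± 44.7 CPM, log2 fold change 4.3 ± 0.20) and the itaconate-synthesis homolog irg1l (ENSDARG00000062788, 4.53 ± 1.40 to 74.1 ± 11.7 CPM, log2 fold change 4.05 ± 0.19) followed with the phosphoprotein gene scpp8 (ENSDARG00000093124, 0.774 ± 0.272 to 14.7 ± 1.90 CPM, log2 fold change 4.24 ± 0.18). Complement c4b (ENSDARG00000038424, 37.9 ± 15.7 to 273 ± 19.9 CPM, log2 fold change 2.84 ± 0.26) and the extracellular chaperone clusterin, clu (ENSDARG00000010434, 37.8 ± 7.28 to 249.6 ± 18.1 CPM, log2 fold change 2.72 ± 0.11) were the most abundant of the 12 after the change together with timp2. The others were the egg yolk precursor vtg7 (ENSDARG00000092419, 3.47), mfap4.8 (ENSDARG00000093877, 2.84), tnfaip2b (ENSDARG00000058160, 2.82), the monooxygenase moxd1 (ENSDARG00000031136, 2.82) and the small GTPase arf4b (ENSDARG00000100339, 2.73). The edgeR adjusted p of the 12 was at most 6.57e-05.

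Of the 12 genes that fell most, 8 encode secreted digestive enzymes. The elastases ela2 (ENSDARG00000056744, 248 ± 37.3 to 38.7 ± 6.67 CPM, log2 fold change -2.68 ± 0.13), ela2l (ENSDARG00000056765, -2.71) and ela3l (ENSDARG00000007276, 365 ± 65.8 to 65.6 ± 12.2 CPM, log2 fold change -2.48 ± 0.15) fell together with the chymotrypsinogen ctrb.2 (ENSDARG00000093844, 155 ± 33.2 to 22.9 ± 4.76 CPM, log2 fold change -2.76 ± 0.18). The amylases amy2a (ENSDARG00000013856, -2.55) and amy2al2 (ENSDARG00000009443, -2.31) and the astacin protease c6ast4 (ENSDARG00000052578, -2.26) fell as well. The others were the heme-binding plasma protein hemopexin, hpxa (ENSDARG00000012609, 15.5 ± 2.84 to 1.48 ± 0.513 CPM, log2 fold change -3.36 ± 0.19), the activity-dependent neuronal transcription factor npas4 (ENSDARG00000055752, 58.0 ± 10.8 to 9.76 ± 0.734 CPM, log2 fold change -2.57 ± 0.12), the carotenoid oxygenase bco1l (ENSDARG00000103659, -2.49), and elovl2 (ENSDARG00000045414, -2.42), which elongates polyunsaturated fatty acids. The edgeR adjusted p of the 12 was at most 5.16e-07. Elastase, amylase and chymotrypsinogen genes have close copies, so the split of reads among copies is uncertain.

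Most genes of the spliceosome rose, and so did most of those of the tri-snRNP that Usp39 works with. Among 33 tri-snRNP and U4/U6 components, 24 rose and 9 did not pass the edgeR test (adjusted over the list alone, 25 rose). Tri-snRNP and U4/U6 components had a median log2 fold change of 0.60, camera adjusted p = 2.41e-16 and adjusted p = 0.0627 with an estimated correlation. The U4/U6 proteins prpf3 (ENSDARG00000086425, 27.8 ± 0.892 to 70.9 ± 3.53 CPM, log2 fold change 1.35 ± 0.07) and prpf31 (ENSDARG00000095904, 16.1 ± 0.406 to 42.3 ± 2.63 CPM, log2 fold change 1.39 ± 0.07) rose, and so did the tri-snRNP proteins snrnp27 (ENSDARG00000035625, 1.24) and eftud2 (ENSDARG00000012261, 1.13). Of 79 other core spliceosome components, 53 rose, 6 fell and 20 did not pass the edgeR test (adjusted over the list alone, 54 rose and 7 fell). The other spliceosome components had a median log2 fold change of 0.32, camera adjusted p = 2.61e-11 and adjusted p = 0.0641 with an estimated correlation. They included the U2 protein sf3a2 (ENSDARG00000021107, 22.4 ± 1.36 to 56.9 ± 2.32 CPM, log2 fold change 1.34 ± 0.07), the intron-binding helicase aqr (ENSDARG00000016775, 1.2), and the Sm proteins snrpd3 (ENSDARG00000013800, 1.57) and snrpd2 (ENSDARG00000040440, 1.26). The edgeR adjusted p of the named members of both lists was at most 1.63e-08.

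Regulators of splice site choice and of transcript quality control did not pass camera as lists. For 59 SR and hnRNP splicing regulators, 27 rose, 7 fell and 25 did not pass the edgeR test (adjusted over the list alone, 27 rose and 7 fell). SR and hnRNP genes had a median log2 fold change of 0.15 and camera adjusted p = 0.0734. Both genes named hnrnpab, hnrnpab (ENSDARG00000099865, 104 ± 8.75 to 167 ± 11.2 CPM, log2 fold change 0.69 ± 0.08) and hnrnpab (ENSDARG00000007960, 117 ± 8.80 to 168 ± 7.52 CPM, log2 fold change 0.53 ± 0.07) rose, as did srsf10b (ENSDARG00000086411, 0.66), while the kinase of SR proteins clk4a (ENSDARG00000089372, -0.51) fell. In the list of nonsense-mediated decay and exon junction genes, which remove transcripts with early stop codons, 5 rose, 1 fell and 11 did not pass the edgeR test (adjusted over the list alone, 5 rose and 1 fell). Decay and junction genes had a median log2 fold change of 0.13 and camera adjusted p = 0.318. The members that rose were eif4a3 (0.67), rbm8a (0.42), upf3b (0.31), smg5 (0.34) and casc3 (0.25), and upf3a (-0.66) fell. The SR and hnRNP list passed the threshold without gfp replicate 1 (camera adjusted p = 0.0364), without a low-count filter (0.0332) and with limma-voom (0.0266). casc3 lost its call without gfp replicate 2 or usp39 replicate 3 (edgeR adjusted p 0.0539 to 0.0824).

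In the p53 pathway and among genes for chaperones of the endoplasmic reticulum (ER) and for ER-associated degradation, more members rose than fell. In the p53 pathway, 26 of 49 members rose, 5 fell and 18 did not pass the edgeR test (adjusted over the list alone, 28 rose and 6 fell). P53 pathway genes had a median log2 fold change of 0.25, camera adjusted p = 5.83e-07 and adjusted p = 0.0641 with an estimated correlation. The ubiquitin ligase mdm2 (ENSDARG00000033443, 30.1 ± 1.17 to 82.1 ± 5.39 CPM, log2 fold change 1.45 ± 0.07) and the TNF receptor tnfrsf1a (ENSDARG00000018569, 1.65) rose, with edgeR adjusted p at most 3.85e-09. Members that fell were tp53i11 (ENSDARG00000006025, -0.44), mdm4 (-0.30), gadd45a (ENSDARG00000104571, -0.66), zmat3 (-0.55) and rrm2b (-0.26). Of 58 genes for ER chaperones and ER-associated degradation, 37 rose, 3 fell and 18 did not pass the edgeR test (adjusted over the list alone, 40 rose and 3 fell). These ER genes had a median log2 fold change of 0.31, camera adjusted p = 9.98e-08 and adjusted p = 0.312 with an estimated correlation. The main ER chaperone BiP, hspa5 (ENSDARG00000103846, 157 ± 27.12 to 403 ± 40.6 CPM, log2 fold change 1.36 ± 0.11) rose with hyou1 (ENSDARG00000013670, 1.01), calr3a (ENSDARG00000103979, 0.85) and dnajb9 (ENSDARG00000016886, 1.33), while pdia2 (-1.27), ern1 (-0.50) and sec61a1 (ENSDARG00000021669, -0.19) fell. Pdia2 is a chaperone of the pancreas. sec61a1 (ENSDARG00000021669) lost its call without gfp replicates 2, 3 or 4 or usp39 replicates 3 or 4 (edgeR adjusted p 0.0563 to 0.0719).

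Targets of the transcription factor ATF4, which acts when translation initiation is restrained, showed the same direction. Among 52 members, 34 rose, 4 fell and 14 did not pass the edgeR test (adjusted over the list alone, 36 rose and 5 fell). The ATF4 targets had a median log2 fold change of 0.39, camera adjusted p = 3.14e-08 and adjusted p = 0.170 with an estimated correlation. The mitochondrial folate enzyme mthfd1l (ENSDARG00000042221, 18.7 ± 1.104 to 80.5 ± 10.5 CPM, log2 fold change 2.1 ± 0.09), the transcription factor cebpb (ENSDARG00000042725, 27.11 ± 6.41 to 89.0 ± 11.07 CPM, log2 fold change 1.71 ± 0.14) and the aminoacyl-tRNA synthetases nars1 (ENSDARG00000061100, 0.80) and tars1 (ENSDARG00000013250, 0.76) rose, whereas stc2 (ENSDARG00000056680, -0.57), slc7a11 (-0.39), vldlr (-0.32, groups overlapping) and chac1 (-0.20) fell. In the cytosolic heat shock list of 57 genes, 30 rose, 6 fell and 21 did not pass the edgeR test (adjusted over the list alone, 33 rose and 7 fell). Heat shock genes had a median log2 fold change of 0.26, camera adjusted p = 0.00125 and adjusted p = 0.464 with an estimated correlation. The myosin chaperone unc45b (ENSDARG00000008433, 25.4 ± 2.37 to 60.1 ± 9.54 CPM, log2 fold change 1.24 ± 0.10), the mitochondrial chaperonin hspd1 (ENSDARG00000056160, 0.79), hspb6 (ENSDARG00000077236, 0.89) and the Hsp90 co-chaperone ptges3 (ENSDARG00000089626, 0.69) rose. The stress-inducible Hsp70 genes hsp70l (-0.98, groups overlapping) and hsp70.1 (-1.19, groups overlapping) were among the 6 that fell and were chosen after their values were seen. hsp70l lost its call without gfp replicates 1 or 2 or usp39 replicate 1 (edgeR adjusted p 0.0728 to 0.114), and without a low-count filter or with the replicate block (adjusted p 0.0621 to 0.187). hsp70.1 lost its call without gfp replicates 1 or 2 or usp39 replicates 1 or 2 (edgeR adjusted p 0.0571 to 0.112), and without a low-count filter or with the replicate block (adjusted p 0.0871 to 0.186). chac1 lost its call without gfp replicates 2 or 3 or usp39 replicates 1 or 2 (edgeR adjusted p 0.0614 to 0.0759).

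Nearly all proteasome subunits rose, while genes of ubiquitin-dependent quality control rose in part. Of 50 proteasome subunits, 46 rose and 4 did not pass the edgeR test (adjusted over the list alone, 46 rose). Proteasome subunits had a median log2 fold change of 0.53, camera adjusted p = 2.88e-17 and adjusted p = 0.139 with an estimated correlation. The catalytic subunits psmb5 (ENSDARG00000075445, 42.1 ± 2.68 to 72.4 ± 1.35 CPM, log2 fold change 0.78 ± 0.07) and psmb6 (ENSDARG00000002240, 24.6 ± 1.14 to 43.4 ± 1.84 CPM, log2 fold change 0.82 ± 0.07) and the regulatory subunits psmc1b (ENSDARG00000043561, 0.74) and psmd7 (ENSDARG00000102417, 0.80) had edgeR adjusted p of at most 4.55e-07. Of 63 genes for ubiquitin and ubiquitin-dependent quality control, 27 rose, 4 fell and 32 did not pass the edgeR test (adjusted over the list alone, 27 rose and 4 fell). Ubiquitin genes had a median log2 fold change of 0.16, camera adjusted p = 0.00874 and adjusted p = 0.128 with an estimated correlation. The segregase vcp (ENSDARG00000020008, 183 ± 5.37 to 289 ± 11.5 CPM, log2 fold change 0.66 ± 0.07), the shuttle factor ubqln4 (ENSDARG00000052975, 0.55), the conjugating enzyme ube2na (ENSDARG00000008748, 0.55) and the proteasome-bound deubiquitinase usp14 (ENSDARG00000025889, 0.65) rose, and hectd4 (-0.35, groups overlapping), ubr1 (ENSDARG00000060480, -0.27), ubr1 (ENSDARG00000104306, -0.26, groups overlapping) and ubxn7 (-0.25, groups overlapping) fell. ubxn7 lost its call without gfp replicate 1 or usp39 replicates 2, 3 or 4 (edgeR adjusted p 0.0538 to 0.0818). ubr1 (ENSDARG00000060480) lost its call without gfp replicate 4 or usp39 replicates 2 or 4 (edgeR adjusted p 0.0536 to 0.0773). ubr1 (ENSDARG00000104306) lost its call without usp39 replicate 4 (edgeR adjusted p 0.0786).

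In the autophagy and lysosome list of 86 genes, 30 rose, 14 fell and 42 did not pass the edgeR test (adjusted over the list alone, 30 rose and 14 fell). These autophagy genes had a median log2 fold change of 0.07, camera adjusted p = 0.0248 and adjusted p = 0.250 with an estimated correlation (exact permutation p of the median 0.0857 over the 35 splits of the libraries). The members with the lowest p were lysosomal cathepsins, ctss2.1 (ENSDARG00000074656, 1.86 ± 0.245 to 9.69 ± 0.869 CPM, log2 fold change 2.38 ± 0.13), ctsla (ENSDARG00000007836, 239 ± 22.9 to 620.3 ± 27.16 CPM, log2 fold change 1.37 ± 0.08) and ctsk (ENSDARG00000040251, 1.68), and the autophagy receptor p62, sqstm1 (ENSDARG00000075014, 39.4 ± 3.37 to 76.8 ± 2.08 CPM, log2 fold change 0.96 ± 0.07). For receptors of ER-phagy, the autophagy of the ER, and genes of UFMylation, 9 of 30 members rose, 4 fell and 17 did not pass the edgeR test (adjusted over the list alone, 9 rose and 4 fell). ER-phagy and UFMylation genes had a median log2 fold change of 0.13, camera adjusted p = 0.311, fry adjusted p = 0.00128 and exact permutation p = 0.0286. Besides sqstm1, rtn4a (ENSDARG00000044601, 0.41) rose. Genes of ER membrane proteins linked to ER-phagy, trim13 (-1.04), atl1 (-0.58), rtn3 (-0.45) and retreg3 (-0.29, groups overlapping), fell. The autophagy call was lost with limma-voom (camera adjusted p = 0.0662) and with protein-coding genes only (0.0616). The autophagy and ER-phagy lists share 3 genes. retreg3 lost its call without gfp replicate 3 (edgeR adjusted p 0.0575).

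Inflammatory genes had the highest median change of the 47 lists, and most markers of leukocytes rose too. Of 52 acute inflammation genes, 45 rose, 1 fell and 6 did not pass the edgeR test (adjusted over the list alone, 45 rose and 1 fell). Acute inflammation genes had a median log2 fold change of 1.22, camera adjusted p = 1.68e-44 and adjusted p = 0.0111 with an estimated correlation. Besides mmp9, the prostaglandin synthase ptgs2 (ENSDARG00000004539) went from 11.3 ± 1.46 to 42.6 ± 2.32 CPM, and the AP-1 factors fosl2 (ENSDARG00000040623, 32.9 ± 1.77 to 92.2 ± 6.13 CPM, log2 fold change 1.49 ± 0.07) and junb (ENSDARG00000074378, 5.66 ± 0.888 to 24.0 ± 0.825 CPM, log2 fold change 2.08 ± 0.11) rose. The member that fell was the AP-1 gene fosb (-0.94). Of 40 myeloid and lymphoid markers, 27 rose, 3 fell and 10 did not pass the edgeR test (adjusted over the list alone, 29 rose and 3 fell). Myeloid and lymphoid markers had a median log2 fold change of 0.92, camera adjusted p = 2.47e-16 and adjusted p = 0.0111 with an estimated correlation. They included the cytokine il1b (ENSDARG00000098700, 3.04 ± 0.357 to 18.9 ± 3.02 CPM, log2 fold change 2.63 ± 0.14), the leukocyte actin-bundling protein lcp1 (ENSDARG00000023188, 8.41 ± 0.654 to 27.9 ± 2.81 CPM, log2 fold change 1.73 ± 0.10) and the collagenase mmp13a (ENSDARG00000012395, 2.67). The markers that fell, rag1 (-1.05), lck (-0.59, groups overlapping) and ccr9 (ENSDARG00000099738, -0.81, groups overlapping), are genes of lymphocytes. The edgeR adjusted p of the named members that rose was at most 4.06e-09. The lists share 3 genes. ccr9 (ENSDARG00000099738) lost its call without gfp replicates 1, 3 or 4 or usp39 replicates 1, 2 or 4 (edgeR adjusted p 0.0504 to 0.0957). lck lost its call without gfp replicate 4 or usp39 replicates 2 or 3 (edgeR adjusted p 0.0515 to 0.0679).

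Interferon response genes, which act against viruses, rose in part. Of 35 members, 16 rose, 3 fell and 16 did not pass the edgeR test (adjusted over the list alone, 16 rose and 3 fell). Interferon genes had a median log2 fold change of 0.44, camera adjusted p = 0.000430 and adjusted p = 0.303 with an estimated correlation. The transcription factor irf9 (ENSDARG00000016457, 8.17 ± 0.705 to 18.3 ± 1.71 CPM, log2 fold change 1.16 ± 0.10) rose with the effectors mxc (ENSDARG00000024789, 2.18) and isg20 (ENSDARG00000079783, 0.71), while stat2 (-0.36), cxcl20 (-0.56, groups overlapping) and ifit16 (-0.49, groups overlapping) fell. ifit16 lost its call without gfp replicates 2 or 3 or usp39 replicates 1, 2 or 3 (edgeR adjusted p 0.0762 to 0.161), and with DESeq2, with limma-voom or with the replicate block (adjusted p 0.0556 to 0.0699). cxcl20 lost its call without gfp replicate 4 or usp39 replicates 2 or 3 (edgeR adjusted p 0.0603 to 0.0764).

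Genes of cell division and of ribosome assembly rose broadly, whereas no member of the cytosolic ribosomal protein list passed the edgeR test. Of 84 proliferation genes, 73 rose, 1 fell and 10 did not pass the edgeR test (adjusted over the list alone, 75 rose and 1 fell). Proliferation genes had a median log2 fold change of 0.48, camera adjusted p = 3.10e-13 and adjusted p = 0.250 with an estimated correlation. The chromatin protein hmgb2 (ENSDARG00000029722, 112 ± 6.34 to 182 ± 7.37 CPM, log2 fold change 0.70 ± 0.07), the replicative helicase subunit mcm5 (ENSDARG00000019507, 0.68), the cytokinesis protein anln (ENSDARG00000060917, 0.74) and rb1 (ENSDARG00000006782, 0.71), a brake on the cell cycle, rose. The member that fell was stmn1 (ENSDARG00000033655, -0.56), which neurons also express. In ribosome biogenesis, 56 of 71 members rose, 2 fell and 13 did not pass the edgeR test (adjusted over the list alone, 61 rose and 2 fell). Biogenesis genes had a median log2 fold change of 0.40, camera adjusted p = 2.73e-09 and adjusted p = 0.355 with an estimated correlation. The nucleolar proteins nolc1 (ENSDARG00000024561, 32.6 ± 2.42 to 56.2 ± 2.79 CPM, log2 fold change 0.79 ± 0.07), nop58 (ENSDARG00000104353, 0.75), nop2 (ENSDARG00000043304, 0.78) and fbl (ENSDARG00000053912, 0.74) rose, and myc (ENSDARG00000007241, -0.31) and ddx21 (-0.22) fell. Among 57 DNA repair genes, 25 rose, 2 fell and 30 did not pass the edgeR test (adjusted over the list alone, 25 rose and 2 fell). Repair genes had a median log2 fold change of 0.24, camera adjusted p = 0.0109 and adjusted p = 0.227 with an estimated correlation. The damage-signalling histone h2ax (ENSDARG00000029406, 0.70), the kinase atr (ENSDARG00000079625, 0.61) and the mismatch repair gene msh6 (ENSDARG00000104541, 0.54) rose, and mre11 (-0.76) and tp53bp1 (-0.19, groups overlapping) fell. None of 76 cytosolic ribosomal protein genes passed the edgeR or the DESeq2 test, 1 passed limma-voom and 1 had an unadjusted edgeR p under 0.05 (median log2 fold change 0.05 and camera adjusted p = 0.541). The lowest p values were those of rpl22 (ENSDARG00000070437, 0.22, groups overlapping), rpl11 (ENSDARG00000043509, 0.19, groups overlapping), rpl12 (ENSDARG00000006691, -0.17, groups overlapping) and rplp2 (ENSDARG00000101406, 0.17, groups overlapping). rpl12 gained a call without gfp replicate 1 (edgeR adjusted p 0.0132), and with library-size scaling or with the replicate block (adjusted p 0.0137 to 0.0492). rpl22 gained a call without gfp replicate 2 or usp39 replicate 1 (edgeR adjusted p 0.0191 to 0.0206), and without a low-count filter, with limma-voom or with the replicate block (adjusted p 0.00314 to 0.0491). tp53bp1 lost its call without gfp replicates 1, 3 or 4 or usp39 replicates 2, 3 or 4 (edgeR adjusted p 0.0825 to 0.124), and without a low-count filter or with limma-voom (adjusted p 0.0541 to 0.0561). rpl11 gained a call without gfp replicate 2 or usp39 replicate 1 (edgeR adjusted p 0.0216 to 0.0337), and with the replicate block (adjusted p 0.00456). rplp2 gained a call without usp39 replicate 1 (edgeR adjusted p 0.0330), and with the replicate block (adjusted p 0.0255). ddx21 lost its call without gfp replicate 4 or usp39 replicates 1 or 4 (edgeR adjusted p 0.0632 to 0.0875).

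Metabolic genes moved in different directions, with sterol synthesis lower and few changes among genes of mitochondrial respiration. Of 30 sterol biosynthesis genes, 16 fell and 14 did not pass the edgeR test (adjusted over the list alone, 1 rose and 16 fell). Sterol genes had a median log2 fold change of -0.30, camera adjusted p = 0.000776 and adjusted p = 0.316 with an estimated correlation. They included the enzymes sqle (ENSDARG00000079946, 8.12 ± 1.11 to 4.00 ± 0.298 CPM, log2 fold change -1.01 ± 0.13), dhcr7 (ENSDARG00000103226, 37.9 ± 4.29 to 22.7 ± 2.29 CPM, log2 fold change -0.74 ± 0.09), lss (ENSDARG00000061274, -1.03) and hmgcs1 (ENSDARG00000103025, -0.79), each of the cholesterol pathway. In glycolysis, 7 of 33 members rose, 15 fell and 11 did not pass the edgeR test (adjusted over the list alone, 7 rose and 15 fell). Glycolysis genes had a median log2 fold change of -0.10, camera adjusted p = 0.0377 and adjusted p = 0.483 with an estimated correlation (exact permutation p of the median 0.114 over the 35 splits of the libraries). The liver-type pyruvate kinase pklr (ENSDARG00000042010, 134 ± 8.94 to 50.5 ± 4.19 CPM, log2 fold change -1.41 ± 0.08), the glucose transporter slc2a1 (ENSDARG00000001437, -1.81) and eno1 (ENSDARG00000013750, -0.81) fell, while hexokinase hk2 (ENSDARG00000101482, 13.2 ± 1.68 to 32.7 ± 3.13 CPM, log2 fold change 1.3 ± 0.10) rose. The glycolysis call was lost without gfp replicate 2 and without usp39 replicates 1, 2 or 4, with camera adjusted p of 0.0637, 0.0743, 0.0536 and 0.0617, and with limma-voom (adjusted p = 0.0746). For oxidative phosphorylation genes of the nucleus, 11 of 79 rose, 3 fell and 65 did not pass the edgeR test (adjusted over the list alone, 1 rose and 1 fell). These respiratory genes had a median log2 fold change of 0.09 and camera adjusted p = 0.317. The ATP synthase gene atp5mc3 (ENSDARG00000017775, 0.33) and the complex I gene ndufb7 (ENSDARG00000033789, 0.36, groups overlapping) rose, and the genes that fell were cox6a1 (ENSDARG00000054588, -0.83), cox6b1 (-0.34, groups overlapping) and cox4i2 (-0.25, groups overlapping). Of 13 mitochondrially encoded genes, mt-nd1 (ENSDARG00000063895, 0.28) rose and 12 did not pass the test (median log2 fold change 0.11 and camera adjusted p = 0.468). It did not pass without usp39 replicate 4 (edgeR adjusted p = 0.0611) or adjusted over the list alone. cox6b1 lost its call without gfp replicates 2 or 4 or usp39 replicates 1 or 2 (edgeR adjusted p 0.0519 to 0.0682). cox4i2 lost its call without gfp replicate 3 or usp39 replicates 2 or 4 (edgeR adjusted p 0.0560 to 0.0773).

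Most genes of the circadian clock were lower. Of 39 clock genes, 5 rose, 28 fell and 6 did not pass the edgeR test (adjusted over the list alone, 6 rose and 29 fell). Clock genes had a median log2 fold change of -0.43, camera adjusted p = 1.09e-07 and adjusted p = 0.303 with an estimated correlation. The nuclear receptors nr1d1 (ENSDARG00000033160, 79.0 ± 6.29 to 29.7 ± 3.98 CPM, log2 fold change -1.41 ± 0.09), nr1d2 (ENSDARG00000009594, -0.77) and rorca (ENSDARG00000057231, -0.90) and the clock output factor dbpb (ENSDARG00000057652, 70.5 ± 6.15 to 32.7 ± 2.78 CPM, log2 fold change -1.11 ± 0.08) fell, while nfil3 (0.80), bmal2 (0.41), tefa (0.41), per2 (0.24) and cry3b (0.25, groups overlapping) rose. The labels give no time of day for any sample. In the hypoxia response list, 13 of 34 members rose, 9 fell and 12 did not pass the edgeR test (adjusted over the list alone, 13 rose and 9 fell). Hypoxia genes had a median log2 fold change of 0.08 and camera adjusted p = 0.0987. Both genes named adm, for the vasodilator adrenomedullin, adm (ENSDARG00000015263, 8.46 ± 1.11 to 41.8 ± 1.37 CPM, log2 fold change 2.30 ± 0.09) and adm (ENSDARG00000069027, 8.33 ± 1.01 to 29.1 ± 4.91 CPM, log2 fold change 1.81 ± 0.12) and the glycolytic regulator pfkfb3 (ENSDARG00000001953, 1.41) rose, and slc2a1 fell. This list passed the threshold without usp39 replicate 2 (camera adjusted p = 0.0406) and without a low-count filter (0.0459). cry3b lost its call without gfp replicates 2, 3 or 4 or usp39 replicates 1, 3 or 4 (edgeR adjusted p 0.0671 to 0.131), and with RLE scaling, with upper-quartile scaling, with library-size scaling, with DESeq2, with limma-voom, without mitochondrial and rRNA genes or with protein-coding genes only (adjusted p 0.0529 to 0.0910).

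Most markers of photoreceptors and of the lens were lower. Of 70 photoreceptor markers, 61 fell and 9 did not pass the edgeR test (adjusted over the list alone, 61 fell). Photoreceptor markers had a median log2 fold change of -1.05, camera adjusted p = 1.32e-35 and adjusted p = 0.112 with an estimated correlation. The cone opsins opn1mw1 (ENSDARG00000097008, 676 ± 32.3 to 182 ± 21.8 CPM, log2 fold change -1.89 ± 0.09) and opn1sw2 (ENSDARG00000017274, 416 ± 33.6 to 101 ± 16.7 CPM, log2 fold change -2.05 ± 0.10), the cone transducin subunit gnb3b (ENSDARG00000002696, 609 ± 52.1 to 173 ± 24.2 CPM, log2 fold change -1.81 ± 0.10) and the opsin kinase grk1b (ENSDARG00000104685, -2.26) fell, each with an edgeR adjusted p of at most 7.42e-10. Of 32 lens markers, 26 fell and 6 did not pass the edgeR test (adjusted over the list alone, 27 fell). Lens markers had a median log2 fold change of -0.96, camera adjusted p = 2.43e-11 and adjusted p = 0.303 with an estimated correlation. The crystallins crygm5 (ENSDARG00000041179, 14.3 ± 1.06 to 4.78 ± 0.568 CPM, log2 fold change -1.58 ± 0.11), crygmx (ENSDARG00000053862, -1.29) and both genes named cryba2, cryba2 (ENSDARG00000041925, -1.22) and cryba2 (ENSDARG00000030349, -1.19), fell. Crystallin genes are multi-copy, so values of single copies are uncertain. Markers of the retinal pigment epithelium and Muller glia went both ways: 10 of 24 rose, 10 fell and 4 did not pass the edgeR test (adjusted over the list alone, 10 rose and 10 fell). Their median log2 fold change was 0.04 but their mean -0.12, and camera pointed down (adjusted p = 0.558). The visual cycle genes rpe65 (ENSDARG00000007480, -1.0) and rlbp1a (ENSDARG00000012504, -0.70) and the glutamate transporter slc1a2 (ENSDARG00000052138, -1.17) fell, and the melanosome gene pmela (ENSDARG00000091298, 0.48) rose.

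Most neuron markers were lower, while markers of neural progenitors went both ways. Of 82 neuron markers, 4 rose, 72 fell and 6 did not pass the edgeR test (adjusted over the list alone, 4 rose and 73 fell). Neuron markers had a median log2 fold change of -0.63, camera adjusted p = 6.68e-19 and adjusted p = 0.303 with an estimated correlation. The enzymes that make the transmitter GABA, gad1 (ENSDARG00000027419, 116 ± 13.7 to 44.9 ± 2.62 CPM, log2 fold change -1.36 ± 0.08) and gad2 (ENSDARG00000015537, 154 ± 14.2 to 71.2 ± 8.87 CPM, log2 fold change -1.11 ± 0.09), the kinase camk2a (ENSDARG00000053617, -1.12) and the NMDA receptor subunit grin1 (ENSDARG00000027828, -1.13) fell. Those that rose were tubb4b (0.54), stmn4 (ENSDARG00000043932, 0.48), uchl1 (0.52) and gap43 (0.39), which include tubulin and growth cone genes. Of 24 glia and myelin markers, 5 rose, 12 fell and 7 did not pass the edgeR test (adjusted over the list alone, 5 rose and 13 fell). Glia and myelin markers had a median log2 fold change of -0.33, camera adjusted p = 0.0333 and adjusted p = 0.464 with an estimated correlation. The myelin genes mpz (ENSDARG00000038609, -1.34), mbpa (ENSDARG00000036186, -0.94) and plp1b (ENSDARG00000011929, -1.29) fell, and the astroglial transporter slc1a3 (ENSDARG00000043148, 34.6 ± 2.63 to 90.8 ± 11.13 CPM, log2 fold change 1.40 ± 0.09) rose with cnp (0.46), glul (ENSDARG00000100003, 0.54), s100b (0.55) and gfap (0.37). For neural progenitors, 12 of 45 rose, 11 fell and 22 did not pass the edgeR test (adjusted over the list alone, 12 rose and 11 fell). Neural progenitor markers had a median log2 fold change of 0.10 and camera adjusted p = 0.631. The intermediate filament gene nes (ENSDARG00000088805, 0.74), fabp7 (ENSDARG00000007697, 0.61) and hmgb3 (ENSDARG00000006408, 0.63) rose, and the retinal factor rx1 (ENSDARG00000071684, -1.07) fell.

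Markers of hair cells and the lateral line were lower in part, and most pituitary markers did not pass the test. Of 44 hair cell and lateral line markers, 2 rose, 24 fell and 18 did not pass the edgeR test (adjusted over the list alone, 3 rose and 24 fell). Hair cell and lateral line markers had a median log2 fold change of -0.33, camera adjusted p = 0.000740 and adjusted p = 0.0627 with an estimated correlation. The synaptic protein of hair cells otof (ENSDARG00000030832, -0.89), pvalb8 (ENSDARG00000037790, -0.69) and cabp2b (ENSDARG00000052277, -0.99) fell, while capg (ENSDARG00000099672, 1.13) and stm (0.25, groups overlapping) rose. Capg is an actin-capping protein also made by macrophages. Among 20 pituitary markers, 2 rose, 6 fell and 12 did not pass the edgeR test (adjusted over the list alone, 2 rose and 6 fell). Pituitary markers had a median log2 fold change of -0.15 and camera adjusted p = 0.415. The hormone genes prl (1.40) and pomc (0.74) rose, and isl1 (ENSDARG00000004023, -0.52) and ghrhrb (ENSDARG00000053708, -0.67) fell. stm lost its call without gfp replicates 1, 3 or 4 or usp39 replicates 1, 2, 3 or 4 (edgeR adjusted p 0.0556 to 0.131), and with upper-quartile scaling or with library-size scaling (adjusted p 0.0583 to 0.0650).

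Markers of the exocrine pancreas had the lowest median change of the 47 lists. Of 27 markers, 1 rose, 24 fell and 2 did not pass the edgeR test (adjusted over the list alone, 1 rose and 24 fell). Exocrine pancreas markers had a median log2 fold change of -1.82, camera adjusted p = 4.01e-46 and adjusted p = 0.0627 with an estimated correlation. The trypsinogens prss1 (ENSDARG00000042993, 629 ± 60.0 to 170.3 ± 15.4 CPM, log2 fold change -1.88 ± 0.09) and prss59.2 (ENSDARG00000073742, 646 ± 58.4 to 229 ± 3.51 CPM, log2 fold change -1.49 ± 0.08), the carboxypeptidase cpb1 (ENSDARG00000045442, 438 ± 47.3 to 109 ± 11.3 CPM, log2 fold change -2.01 ± 0.09) and the chymotrypsinogen ctrb.1 (ENSDARG00000090428, -1.55) fell, each with an edgeR adjusted p of at most 4.97e-10. In the same libraries the median log2 fold change of the myeloid and lymphoid markers was 0.92. In the endocrine pancreas, 1 of 17 markers rose, 11 fell and 5 did not pass the edgeR test (adjusted over the list alone, 1 rose and 11 fell). Endocrine pancreas markers had a median log2 fold change of -0.48, camera adjusted p = 0.0145 and adjusted p = 0.303 with an estimated correlation. The prohormone convertase pcsk1 (ENSDARG00000002600, -0.74), isl1 and neurod1 (ENSDARG00000019566, -0.53) fell, all of which other neuroendocrine cells express, and glucagon gene gcga (ENSDARG00000079296, 10.2 ± 1.2 to 17.6 ± 2.92 CPM, log2 fold change 0.79 ± 0.12) rose. Close copies among trypsinogen and chymotrypsinogen genes leave the split of reads between them uncertain.

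Most genes of the absorptive gut epithelium fell, and liver genes moved in both directions. Of 54 enterocyte markers, 3 rose, 42 fell and 9 did not pass the edgeR test (adjusted over the list alone, 3 rose and 43 fell). Enterocyte markers had a median log2 fold change of -0.91, camera adjusted p = 6.68e-19 and adjusted p = 0.227 with an estimated correlation. The peptide transporter slc15a1 (ENSDARG00000044528, 170.0 ± 9.07 to 48.4 ± 8.38 CPM, log2 fold change -1.82 ± 0.10), the bile acid-binding protein fabp6 (ENSDARG00000044566, 130.2 ± 8.79 to 50.9 ± 5.66 CPM, log2 fold change -1.35 ± 0.08) and the uptake receptor cubn (ENSDARG00000087013, -1.01) fell, while dab2 (ENSDARG00000053091, 1.04), agr2 (1.04) and apoa1a (0.46, groups overlapping) rose. Of 87 hepatocyte markers, 17 rose, 53 fell and 17 did not pass the edgeR test (adjusted over the list alone, 18 rose and 54 fell). Hepatocyte markers had a median log2 fold change of -0.40, camera adjusted p = 0.000618 and adjusted p = 0.589 with an estimated correlation. Complement c3a.1 (ENSDARG00000012694, 240.1 ± 31.8 to 866 ± 74.2 CPM, log2 fold change 1.85 ± 0.10) and ceruloplasmin, cp (ENSDARG00000010312, 58.0 ± 4.99 to 164 ± 22.7 CPM, log2 fold change 1.5 ± 0.10), which are made in the acute phase response, rose, whereas the carboxylesterase ces2b (ENSDARG00000101726, 246 ± 29.6 to 80.1 ± 9.74 CPM, log2 fold change -1.62 ± 0.10) and hpxa fell. In the kidney list, 6 of 37 rose, 18 fell and 13 did not pass the edgeR test (adjusted over the list alone, 7 rose and 18 fell). Kidney markers had a median log2 fold change of -0.20 and camera adjusted p = 0.118. The amino acid transporter slc6a19 (ENSDARG00000091560, -1.40) fell with cubn, and the endocytic adaptor dab2 (ENSDARG00000053091, 1.04) and the phosphate transporter slc20a1 (ENSDARG00000010641, 1.08) rose.

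Most skeletal muscle markers were higher, whereas most markers of myogenic progenitors and heart did not pass the edgeR test. Of 66 skeletal muscle markers, 41 rose, 5 fell and 20 did not pass the edgeR test (adjusted over the list alone, 43 rose and 6 fell). Skeletal muscle markers had a median log2 fold change of 0.32, camera adjusted p = 5.20e-05 and adjusted p = 0.513 with an estimated correlation. Creatine kinase ckma (ENSDARG00000035327, 1693 ± 99.7 to 2847 ± 211 CPM, log2 fold change 0.75 ± 0.08), the purine enzyme ampd1 (ENSDARG00000033832, 363 ± 14.4 to 603 ± 25.4 CPM, log2 fold change 0.73 ± 0.07) and the contractile genes tpm3 (ENSDARG00000005162, 0.71) and myl13 (ENSDARG00000042245, 0.66) rose, whereas mybpc2 (-1.05), tnnc2.1 (-1.45), mybpc1 (-0.70), mybpc2b (-0.31, groups overlapping) and cacng1 (ENSDARG00000052360, -0.97) fell. For myogenic progenitors, 5 of 17 rose, 3 fell and 9 did not pass the edgeR test (adjusted over the list alone, 5 rose and 3 fell). Myogenic progenitor markers had a median log2 fold change of 0.12 and camera adjusted p = 0.401. The somite factor meox1 (ENSDARG00000007891, 1.22) rose with met (0.54), pax3 (ENSDARG00000010192, 0.56), pax7 (ENSDARG00000070818, 0.34) and pax3 (ENSDARG00000028348, 0.49, groups overlapping), and the fusion factor mymx (ENSDARG00000099437, -0.53) fell with mef2c (ENSDARG00000009418, -0.28) and myog (-0.26). Of 23 heart markers, 5 rose and 18 did not pass the edgeR test (adjusted over the list alone, 4 rose). Heart markers had a median log2 fold change of 0.07 and camera adjusted p = 0.394. Those that rose were myl10 (0.62), tnni1 (ENSDARG00000052708, 0.64), nppb (0.79), tnnt2 (ENSDARG00000020610, 0.41) and myh6 (ENSDARG00000114031, 0.22, groups overlapping). Erythroid markers went both ways: 8 of 31 rose, 5 fell and 18 did not pass the edgeR test (adjusted over the list alone, 8 rose and 5 fell). Erythroid markers had a median log2 fold change of 0.07 and camera adjusted p = 0.631. The globin hbae3 (ENSDARG00000079305, 0.56) and epb41b (ENSDARG00000029019, 0.48) rose, and ank1 (ENSDARG00000074777, -0.73), hbae5 (-0.61), ank1 (ENSDARG00000059093, -0.34), rhag (-0.32, groups overlapping) and tal1 (-0.29, groups overlapping) fell. Globin genes have close copies, so single values are uncertain. myh6 (ENSDARG00000114031) lost its call without gfp replicates 1 or 4 or usp39 replicates 2, 3 or 4 (edgeR adjusted p 0.0796 to 0.123), and with upper-quartile scaling, with library-size scaling or with DESeq2 (adjusted p 0.0515 to 0.0684). cacng1 (ENSDARG00000052360) lost its call without gfp replicates 1 or 3 or usp39 replicates 1, 3 or 4 (edgeR adjusted p 0.0504 to 0.163), and without a low-count filter or with DESeq2 (adjusted p 0.0629 to 0.0836). tal1 lost its call without gfp replicate 1 or usp39 replicates 2 or 3 (edgeR adjusted p 0.0513 to 0.0666). myog lost its call without gfp replicates 2 or 4 or usp39 replicates 1, 2, 3 or 4 (edgeR adjusted p 0.0577 to 0.148). pax3 (ENSDARG00000028348) lost its call without gfp replicate 4 or usp39 replicate 2 (edgeR adjusted p 0.0515 to 0.0986).

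Matrix, skin and vessel genes showed mixed changes. Of 57 genes for fibroblast and basement membrane matrix, 26 rose, 10 fell and 21 did not pass the edgeR test (adjusted over the list alone, 27 rose and 10 fell). These matrix genes had a median log2 fold change of 0.16, camera adjusted p = 0.0117 and adjusted p = 0.624 with an estimated correlation (exact permutation p of the median 0.0571 over the 35 splits of the libraries). Both fibronectin genes, fn1 (ENSDARG00000019815, 99.0 ± 6.63 to 216 ± 14.2 CPM, log2 fold change 1.12 ± 0.07) and fn1 (ENSDARG00000006526, 727 ± 68.3 to 1193 ± 80.3 CPM, log2 fold change 0.72 ± 0.08) and lama1 (ENSDARG00000102277, 0.98) and col12a1 (ENSDARG00000078322, 0.72) rose. Of 43 cartilage and bone markers, 4 rose, 16 fell and 23 did not pass the edgeR test (adjusted over the list alone, 4 rose and 15 fell). Cartilage and bone markers had a median log2 fold change of -0.14, camera adjusted p = 0.0238 and adjusted p = 0.507 with an estimated correlation (exact permutation p of the median 0.0571 over the 35 splits of the libraries). The bone matrix gene spp1 (ENSDARG00000044276, -1.2), the cartilage collagen col9a3 (ENSDARG00000037845, -0.69) and the aggrecans acana (ENSDARG00000035891, -0.52) and acanb (ENSDARG00000045799, -0.51) fell, and sox9 (ENSDARG00000043923, 0.38), matn3 (ENSDARG00000069265, 0.49), hapln1a (0.34) and col9a1b (0.48, groups overlapping) rose. The cartilage and bone call was lost without gfp replicate 2 (camera adjusted p = 0.0583). In the epidermis, 23 of 64 markers rose, 18 fell and 23 did not pass the edgeR test (adjusted over the list alone, 23 rose and 20 fell). Epidermis markers had a median log2 fold change of 0.08 and camera adjusted p = 0.339. Epithelial adhesion genes epcam (ENSDARG00000040534, 1.0) and cdh1 (ENSDARG00000102750, 0.95) and the keratin krt18b (ENSDARG00000028618, 1.09) rose, and sult6b1 (ENSDARG00000086826, -1.04) fell. Among 37 pigment cell markers, 15 rose, 5 fell and 17 did not pass the edgeR test (adjusted over the list alone, 15 rose and 5 fell). Pigment cell markers had a median log2 fold change of 0.16 and camera adjusted p = 0.339. The receptor csf1ra (ENSDARG00000102986, 1.05), which macrophages also carry, rose, and scarb1 (-1.2), xdh (-0.96), fhl2 (ENSDARG00000003991, -0.97), trpm1b (-0.70) and kit (-0.31) fell. For endothelium, 8 of 38 rose, 6 fell and 24 did not pass the edgeR test (adjusted over the list alone, 8 rose and 5 fell). Endothelium markers had a median log2 fold change of -0.03 and camera adjusted p = 0.456. Its mean log2 fold change was 0.06 and camera pointed up, against the sign of the median. The lymphatic receptor lyve1a (ENSDARG00000075833, 2.48 ± 0.929 to 11.8 ± 0.613 CPM, log2 fold change 2.25 ± 0.18) rose with plvapb (ENSDARG00000045003, 0.87) and both genes named cldn5, cldn5 (ENSDARG00000014059, 0.72) and cldn5 (ENSDARG00000043716, 0.66). col9a1b lost its call without gfp replicate 2 (edgeR adjusted p 0.0532).

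**Figure D3:**
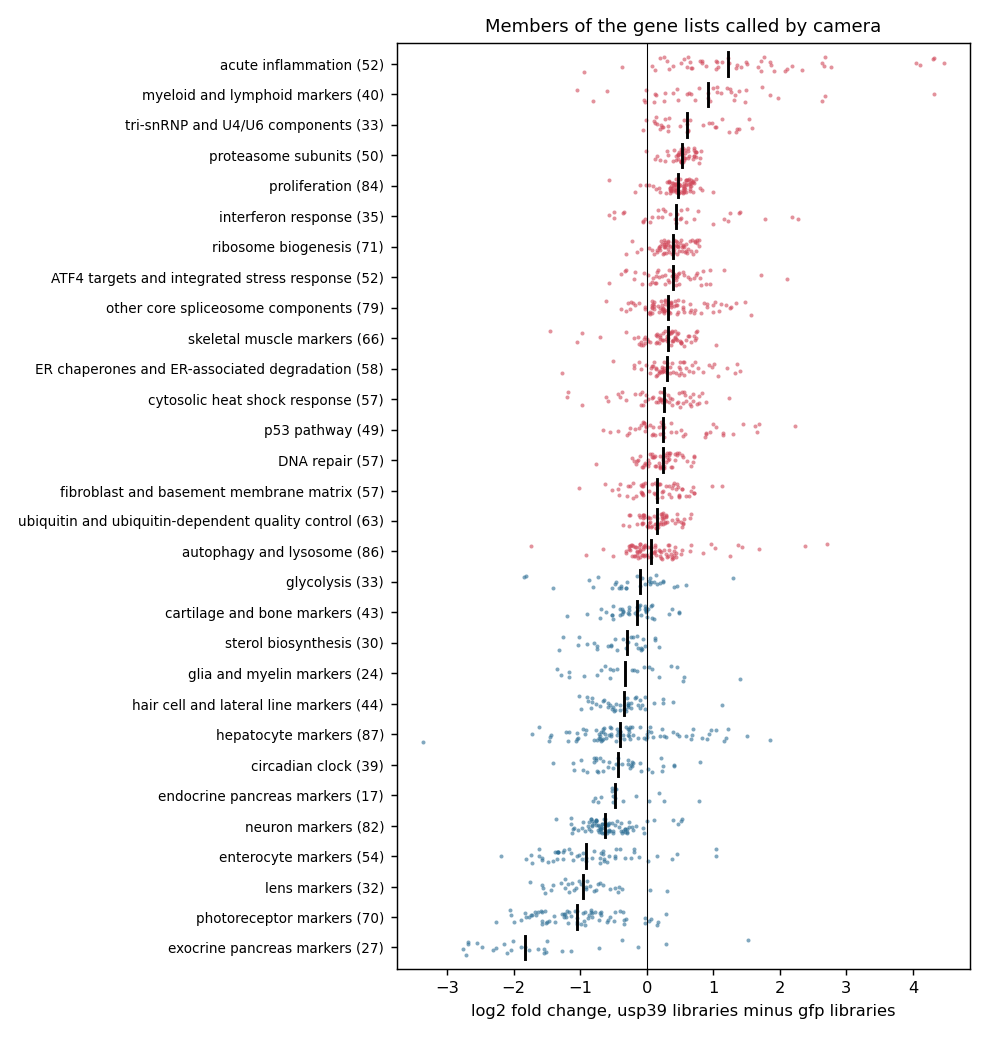
Points are the measured members of the 30 lists that camera called (number of members in parentheses), placed by log2 fold change (usp39 minus gfp libraries), and black bars are medians. Medians ran from -1.82 for exocrine pancreas markers to 1.22 for acute inflammation.

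**Figure D4:**
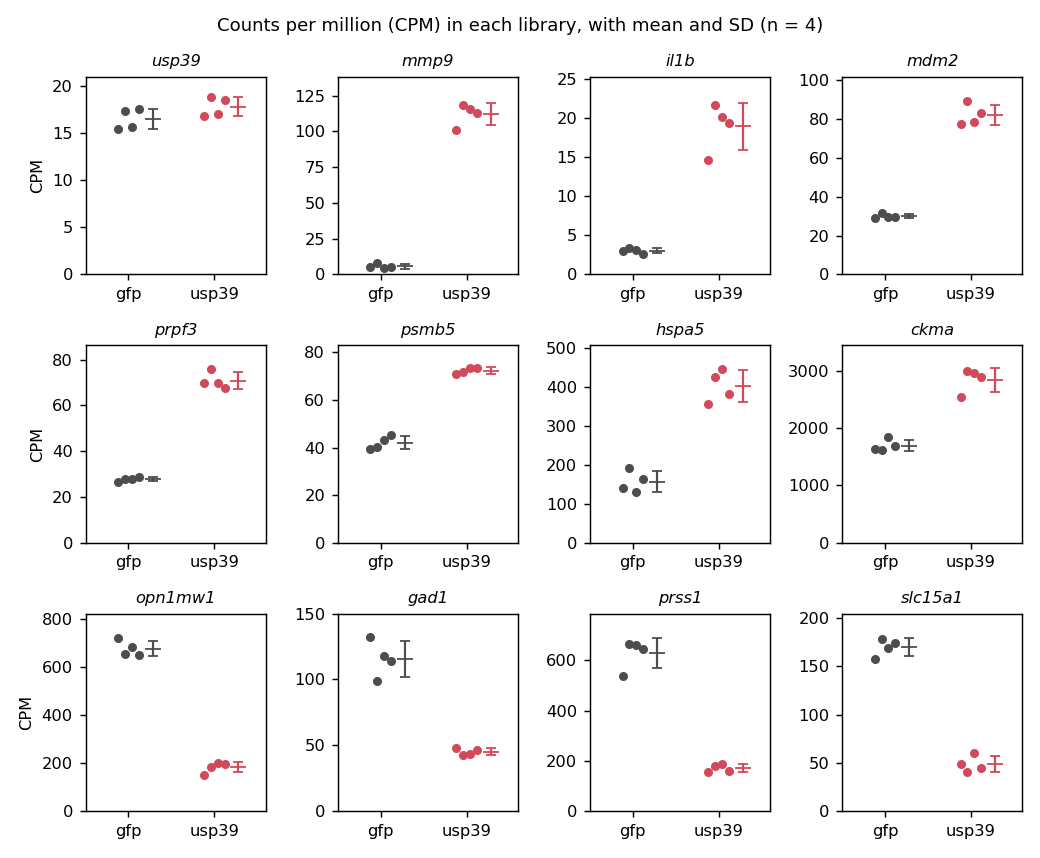
Each point is the CPM of 1 gene in 1 library, grey for gfp and red for usp39, with bars at the mean ± SD of 4 libraries. Usp39 stood at 16.5 and 17.8 CPM in the groups, whereas the 4 usp39 libraries lay wholly above gfp for mmp9, il1b, mdm2, prpf3, psmb5, hspa5 and ckma and wholly below for opn1mw1, gad1, prss1 and slc15a1.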

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

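The tests of a wrong label, of too few reads, of exchanged labels, of scaling and of leukocyte RNA in this part were chosen only after the result was seen. The usp39 transcript was not lower in the libraries labelled usp39. A single misplaced library is argued against, since 8 of 8 correlated best across genes with a library of their own group. Too few reads is argued against by the lower bound of the 95% interval of the log2 fold change, -0.0693, which lies above the -1 that a 2-fold fall would give. An exchange of all labels with a 2-fold fall is argued against by the upper bound, 0.289, which lies below the 1 it would give. An exchange with a smaller fall or none stays open, as does, untested, an edit or a morpholino that leaves the transcript level unchanged.

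Reads outside annotated genes made up a smaller share in the usp39 libraries. Genomic DNA in the gfp libraries stays open. Counts on the 8130 genes of lowest mean CPM (at most 0.511) summed to 1295 ± 16.9 CPM in gfp and 1134 ± 33.0 in usp39 (SD, n = 4). The difference was -161 (exact permutation p = 0.0286). This fall was predicted beforehand but is not specific to DNA. A biological difference in transcription, outside genes or by tissue, could also move rarely counted genes and stays open. A difference in unspliced or intronic RNA was not tested, since counts per gene do not show introns.

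Markers of exocrine pancreas, photoreceptors, lens, enterocytes and neurons were lower. Scaling as the source of their difference from other tissues is argued against, since a factor per library moves all lists alike: with any 1 library left out the skeletal muscle median stayed at least 0.840 (log2) above each of these 5 medians. Leukocyte RNA that dilutes every other tissue alike is argued against by skeletal muscle markers, whose lowest median with any 1 library left out was 0.28. Fewer such cells, a lower level per cell, or a delay in development, for which no stage is given in the labels, stay open and were not tested.

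Single libraries stood apart from the other 3 of their group, by Dixon's ratio of gap to range at its 95% critical value, for 34 of 602 groups of 4 values (the 291 genes named in the text and 10 library measures in each group). Chance alone gives about 1 in 20, here 30.1. Values are CPM. Gfp replicate 1 lay below the rest of its group for amy2al2 (174, others 229 to 242), rbm8a (23.3, others 25.9 to 26.3), mybpc2 (13.2, others 17.4 to 18.4), prss1 (539, others 647 to 666) and kit (37.97, others 41.5 to 41.9) and above it for sox9 (ENSDARG00000043923, 40.7, others 35.6 to 36.1). Gfp replicate 2 lay below the rest of its group for crygm5 (12.7, others 14.7 to 14.8), smg5 (34.7, others 41.1 to 41.8) and lama1 (28.3, others 39.8 to 41.7) and above it for usp14 (29.7, others 24.2 to 24.7), ghrhrb (4.17, others 3.84 to 3.89) and cubn (59.3, others 53.6 to 54.2). Gfp replicate 3 lay above the rest of its group for pax3 (ENSDARG00000028348, 3.92, others 3.29 to 3.38), prl (1.252, others 0.574 to 0.619) and rtn3 (364, others 309 to 314). Gfp replicate 4 lay below the rest of its group for stmn1 (ENSDARG00000033655, 288, others 304 to 307) and above it for rrm2b (21.5, others 20.8 to 20.8). The usp39 replicate 1 lay below the rest of its group for irf9 (15.7, others 19.02 to 19.2) and rpl11 (501, others 604 to 625) and above it for grin1 (ENSDARG00000027828, 129, others 115 to 115). The usp39 replicate 2 lay below the rest of its group for sqle (ENSDARG00000079946, 3.56, others 4.11 to 4.21), msh6 (39.7, others 44.7 to 45.2) and cfap90 (0.528, others 1.26 to 1.44) and above it for tars1 (84.7, others 75.8 to 76.8), tnnt2 (ENSDARG00000020610, 23.3, others 18.1 to 18.7) and usp14 (42.5, others 39.6 to 39.8). The usp39 replicate 3 lay above the rest of its group for fn1 (ENSDARG00000006526, 1313, others 1144 to 1164), anln (57.5, others 54.6 to 54.8), vdr (ENSDARG00000070721, 72.6, others 68.0 to 68.5) and trpm1b (30.0, others 26.8 to 27.3). The usp39 replicate 4 lay below the rest of its group for ctss2.1 (8.40, others 9.98 to 10.3) and scarb1 (9.32, others 11.9 to 12.03) and above it for atp5mc3 (78.8, others 68.2 to 69.5). The share of counts on named rRNA genes was 0.0368% in usp39 replicate 2 and 0.0235 to 0.0252% in the other usp39 libraries. Among reads that no comparison of genes used, alignments that were not unique averaged 9.15% in the usp39 libraries, above the gfp range of 7.89 to 8.47%.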

How the results depend on the processing

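Of the tests in this part, RLE scaling for the lists was added after the data were seen. Leaving out each library in turn gave 10600 (without usp39 replicate 4) to 12456 (without gfp replicate 2) changed genes, 5285 to 6277 higher and 5297 to 6179 lower. The usp39 log2 fold change ran from 0.07 to 0.14 and its edgeR adjusted p over all alternatives from 0.232 to 0.560, and 28 to 31 lists were called. Other scalings, filters and tests gave 11539 to 11908 changed genes, protein-coding genes only 10336 and an adjusted p under 0.01 8869. With an absolute log2 fold change of at least 1 as well, 1677 genes passed, fewer by construction. Among genes called both in the report and under an alternative, 0 had the opposite direction under any of these edgeR, DESeq2 or limma-voom settings. Scaling by library size alone moved the median of all genes most, by -0.0338 on the log2 scale, with 46.1% of the changed genes higher against 50.5%.

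Camera with a correlation estimated per list called 2 lists in place of 30. Fry, listed as an alternative for scaling too, called 40. Over all alternatives 880 values of single lists stayed on the same side of the threshold, 43 lost the call and 15 gained it. Apart from the estimated correlation, fry and the stricter threshold, the autophagy, glycolysis, cartilage and bone, SR and hnRNP and hypoxia lists crossed the threshold under single settings, with the values in the report. Camera adjusted p of the autophagy list ran from 0.00810 to 0.250 over the alternatives. The causes were not tested. Of 299 genes besides usp39 that the naming rule took or the text names, 265 kept direction and call under each alternative. These genes lost a call in 124 values, gained one in 13 and stayed the same in 5235.

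With the replicate number as a block, 12485 genes changed (6297 higher and 6188 lower), 30 lists were called and the usp39 log2 fold change was 0.11 (edgeR adjusted p = 0.274). Whether the numbers pair the samples is not known.

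For the number of genes, a chance division of the 8 libraries is argued against, at the smallest exact permutation p that 35 splits allow, 0.0286. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many changed genes, 1 as many higher and 1 as many lower as the real one, with 11950, 6036 and 5914. The highest other split gave 0 by the edgeR test, with up to 4840 genes at an unadjusted p under 0.05. DESeq2 and limma-voom were not run on the splits. For the number of lists chance cannot be excluded by this count: 4 of 35 splits gave at least as many as the real 30, and the highest other gave 31. The 3 others each exchanged 1 library per group and so keep part of the real contrast. Of all 47 lists, 31 had their most extreme median in the real split (exact permutation p = 0.0286, the smallest possible). Of the 30 called, 26 did, all but autophagy, glycolysis, cartilage and bone, and fibroblast matrix.

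At the depth, spread and number of libraries here, simulated genes with the smallest of the 4 folds were recovered in 10% of cases. The planned trend with exon number and the contrast of nested genes were not run.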

Other observations

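Genes of motile cilia were mostly higher in the libraries labelled usp39. Of the tests in this part, those on gene families were chosen only after the report's results were seen, and the genes named were chosen after their values were seen, except the foxj1 genes. Genes were grouped into families by the stem of their symbol, which gave 401 families of at least 8 measured members. Of 39 cilia and flagella associated (cfap) genes, 24 rose, 2 fell and 13 did not pass the edgeR test, with median log2 fold change 0.75, camera adjusted p = 2.03e-06 and adjusted p = 0.571 with an estimated correlation. Examples are cfap57 (ENSDARG00000058090, 6.63 ± 0.512 to 16.8 ± 3.12 CPM, log2 fold change 1.35 ± 0.13), cfap99 (ENSDARG00000097485, 1.3) and cfap100 (ENSDARG00000111474, 1.64), and those that fell were cfap68 (ENSDARG00000101743, -0.79, groups overlapping) and cfap90 (ENSDARG00000115108, -0.72). Of 12 axonemal dynein heavy chain (dnah) genes, 10 rose and 2 fell, with median log2 fold change 0.70, camera adjusted p = 0.000584 and adjusted p = 0.576 with an estimated correlation. The dynein genes dnah6 (ENSDARG00000000606, 13.0 ± 0.899 to 25.4 ± 2.33 CPM, log2 fold change 0.96 ± 0.09) and dnah5l (ENSDARG00000056888, 1.01) rose, and dnah9l (ENSDARG00000062630, -0.86) and dnah3 (ENSDARG00000068468, -0.31) fell. Foxj1 is the transcription factor that switches on motile cilium genes. A higher foxj1 transcript may accompany the higher cilium genes: 1 of 2 foxj1 genes was called higher, foxj1 (ENSDARG00000101919, 5.25 ± 0.555 to 25.6 ± 3.28 CPM, log2 fold change 2.28 ± 0.11), with an edgeR adjusted p of 3.37e-10. The other, foxj1b (ENSDARG00000088290), had a log2 fold change of 0.08 (edgeR adjusted p = 0.685). The foxj1 test had a prediction written before the value was seen and leaves open whether more ciliated cells or more transcript per cell lie behind it. cfap90 lost its call without gfp replicate 3 or usp39 replicate 2 (edgeR adjusted p 0.0701 to 0.0851). cfap68 lost its call without usp39 replicate 1 (edgeR adjusted p 0.0584). dnah3 lost its call without usp39 replicate 2 (edgeR adjusted p 0.0553).

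Other families also moved largely 1 way. Of 26 gamma M crystallin genes of the lens, 25 fell and 1 did not pass the edgeR test (median log2 fold change -1.15), and of 56 protocadherin genes, which act in contacts between neurons, 2 rose, 49 fell and 5 did not pass the edgeR test (-0.42). The protocadherins that rose were pcdh20l (ENSDARG00000101910, 0.54) and pcdh12 (ENSDARG00000076594, 0.32). Of 17 mfap genes, most of them copies of the macrophage-expressed mfap4, 13 rose and 4 did not pass the edgeR test (1.40). All 10 genes of the actin-branching Arp2/3 complex in the arpc family rose (0.51), with arpc5 (ENSDARG00000039142, 1.18) and arpc1b (ENSDARG00000027063, 1.18) among them. Of 80 cytochrome P450 genes, which serve both synthesis and breakdown of lipids, hormones and drugs, 12 rose, 48 fell and 20 did not pass the edgeR test (-0.55), with cyp3a65 (ENSDARG00000103295, -2.18) among those that fell, and of 29 UDP-glucuronosyltransferases, which conjugate drugs and hormones, 22 fell and 7 did not pass the edgeR test (-0.51), ugt1a1 (ENSDARG00000006220, -1.24) among them. Camera with the preset correlation called 77 of the 401 families, these among them. With an estimated correlation camera called 0, with 31 at an unadjusted p under 0.05, and fry called 269. An exact permutation of the libraries gave each family named here p = 0.0286, the smallest possible, and an adjusted p of 0.0559 over the families, which does not pass. Medians of the families named here kept their sign under RLE, upper-quartile and library-size scaling, and reads of near-identical copies are uncertain.

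Enzyme genes of active vitamin D were picked by value and not tested as a list. The hydroxylases of synthesis cyp2r1 (ENSDARG00000056587, 11.5 ± 0.884 to 4.35 ± 0.164 CPM, log2 fold change -1.40 ± 0.11) and cyp27b1 (ENSDARG00000045015, 6.44 ± 1.21 to 1.85 ± 0.0145 CPM, log2 fold change -1.80 ± 0.16) fell, and cyp24a1 (ENSDARG00000103277, 11.01 ± 1.94 to 50.7 ± 14.3 CPM, log2 fold change 2.21 ± 0.19), which inactivates the hormone and is a target of its receptor, rose. The 3 receptor genes named vdr did not pass the edgeR test (adjusted p 0.314, 0.354 and 0.508). The second leptin gene, lepa (ENSDARG00000091085, 0.703 ± 0.205 to 5.22 ± 0.964 CPM, log2 fold change 2.90 ± 0.22), rose as lepb did.

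If the usp39 fish carried an edited allele with a linked haplotype, genes near usp39 on its chromosome could differ more often than genes elsewhere. Among the 100 tested genes nearest to usp39 in RefSeq gene order, 50% had changed, and the median of 13163 windows of 100 genes was 50%. The share lay at percentile 44.7 of the windows. The median size of the log2 fold change was 0.31 against 0.29, at percentile 72.1. Neither reached the 95th percentile, which argues against a linked haplotype as a strong source of changes there, but with so many genes changed everywhere a small excess could not be seen.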
